A study of Arabidopsis thaliana with 16 samples.

How the data were processed

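RNA-seq and EIN2 antibody ChIP-seq of 3-day-old, dark-grown whole seedlings of Arabidopsis thaliana were analysed from the files the authors deposited, with no reads. Per the labels, seedlings grew at 24 °C and were treated for 4 h with air or 10 ppm ethylene. The 16 samples are 6 RNA libraries (3 lines, 2 each), 6 ChIP libraries and 4 inputs. Groups were taken from the sample titles. Some labels conflict: the Col-0 ChIP and input libraries titled air have an agent label of ethylene, the Col-0 ethylene input has a genotype label of ein3-1 eil1-1, and the S645A line is written with EIN2 in its title and with EIN2C in the series design. The text follows the titles. A Col-0 library is therefore "titled air".

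RNA values are FPKM estimates that the authors made with Cuffdiff 2.2.1 on TAIR10, per the submitters' processing notes, as 1 value per line with its replicates pooled. The deposited tables give a log2 fold, a p-value and a q-value per gene, per the file headers. By their names and by their values, the deposited tables keep genes with a fold of at least 2, a level of at least 1 and a q-value under 0.05. The smallest p-value in each deposited table is 5e-05. The role of BWA, named in the submitters' processing notes, and the RNA aligner are not given in the sources used here. Col libraries are not among the samples, and the 3 Col value columns were not used here. The treatment of Col is not given in the sources used here. Col levels implied by the folds differed between tables by constant log2 amounts of 0.41, 0.36 and -0.04, so 1 set of Col values stands behind all 3. Tables were scaled separately, and levels are not compared across them. The K245N table has the line as its first group, per the file headers, and its folds were turned to line over Col. Neither the tested genes nor the depth of RNA libraries is known here.

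Peaks were called by the authors per library with MACS2 2.1.0.20150603 at a p of 0.001 and a genome size of 119000000 bp, per the file headers, without pooling replicates. Per the file headers, both ein3-1 eil1-1 replicates of a treatment share 1 input. The deposited lists give a pileup signal, a fold enrichment (a ratio to local input) and -log10 p and q values for each peak, per the file headers. The comment lines of the same deposited lists say that q was not calculated, but the column named -log10 q holds values of 0 and above. It was read as named, and results at a -log10 q of at least 5 rest on that. Tags kept after removal of duplicates, per the file headers, were 3743192 and 4713282 in Col-0 air and ethylene, 10515608 and 10073282 in ein3-1 eil1-1 air, and 6205149 and 6325081 in ethylene. The share of redundant tags was 0.61 and 0.56 in Col-0, 0.30 and 0.29 in ein3-1 eil1-1 air, and 0.20 in both ethylene libraries. The fragment length was 73 to 79 bp by the authors' model, per the file headers, close to the tag size of 75 bp, so peak widths and summits are approximate. With 1 tag kept per position, pileup could not exceed 2 times the fragment length, and the highest peak of each library reached that limit. Duplicate removal therefore compresses the strongest sites.

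Gene names and neighbours came from a table of the TAIR10.1 assembly, of which no coordinate is printed; 98.1%, 97.6% and 98.6% of listed identifiers were found there. Printed coordinates are those of the deposited files (TAIR10), 1-based. The table holds no strand, so a peak was placed at a gene when it lay in it or within 1000 bp of either end, where the plan was the upstream side. Regions are replicate 1 peaks that overlap a replicate 2 peak by at least 1 bp, and their printed coordinates are the outer limits of the overlapping peaks. Implied input is the pileup plus 1 divided by the fold enrichment, minus 1, and was called high at 3 times the genome mean.

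No test between lines was run, because no values per library were at hand; calls are the authors'. Lists were tested with two-sided Fisher's exact tests of higher against lower among listed genes and of membership among 27444 protein-coding nuclear genes, with Benjamini-Hochberg adjustment over 54 tests. Placements of peaks at lists (72 tests) and at genes called in EIN2C-EIN3DB (8 tests) were handled likewise. Genes are not independent replicates. Peak overlap was set against 1000 random placements on the nuclear chromosomes. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only. A simulation of 1000000 genes with no effect and 1 shared control gave the same-direction share and overlap for comparisons that share Col, with each simulated list called at the share of genes in the real list. An earlier form called 2.5% of genes per direction whatever the list size. Its ratio of 7.35 and share of 99.88% cannot be set beside the lists and are not used. Motifs at summits were not tested, since no genome was at hand.

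The 18 gene lists (205 entries) and the rule for named genes were fixed before the data were examined: EIN2, EIN3 and EIL1 first; the 10 largest increases and decreases per line among genes above 0 in both groups and at least 10 in 1; the 4 listed members with the largest change of each list, and all members of the ethylene signalling and EIN3 target lists; and for peaks the 10 strongest regions found in both replicates and peaks at members of those lists. Genes with peaks in other lists were named after they were seen. The lists cover ethylene signalling, EIN3 targets, EIN3-repressed genes, ethylene biosynthesis, auxin, cell wall loosening, jasmonate and ERF defence, salicylate, photosynthesis, seed storage, heat shock, hypoxia, root hair, cell division, histone acetylation, cytokinin, gibberellin and reference genes. Lists of 10 cold-regulated, 5 ER body and 67 ribosomal protein genes were added after the data were seen and are given as counts without a test, since genes among their members had led to them.

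Alternatives changed the fold, q and level minimum, the peak thresholds, the overlap rule, the flank, the replicate and the background. The code was tested on simulated data. It recovered the planted sharing of 50% among 400 peaks under each overlap rule, gave p under 0.05 in 1% of 100 draws with no sharing, and turned folds the right way for 100% of 2000 genes. The list test gave p under 0.05 in 4% of 200 lists with no effect and in 95.5% of 200 lists with 90% of 15 members lower. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.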

Results

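The samples came from Arabidopsis thaliana seedlings that carried engineered ethylene signalling proteins. EIN2 is a membrane protein whose carboxyl-terminal part, EIN2C, enters the nucleus after ethylene is perceived, and EIN3 is a transcription factor at the head of the ethylene response. By its name, the fusion EIN2C-EIN3DB joins EIN2C to the EIN3 DNA binding domain, K245N is a substitution in the EIN3 part of the fusion, and S645A is a substitution in EIN2. RNA was sequenced from 3 lines in the ein3-1 eil1-1 background, a double mutant of EIN3 and its close relative EIL1, with 2 libraries per line, all from air. Chromatin immunoprecipitation (ChIP) with an EIN2 antibody was sequenced from seedlings that carried EIN2C-EIN3DB in wild-type Col-0 (1 library titled air and 1 titled ethylene) and in ein3-1 eil1-1 (2 libraries in air and 2 in ethylene). There were 4 input libraries without antibody. Seedlings were 3 days old, dark-grown, and treated for 4 h with air or with 10 ppm ethylene. The RNA tables hold 1 value per line, so no replicate spread or per-library depth could be given for RNA. The ChIP libraries kept between 3743192 tags in Col-0 air and 10515608 tags in ein3-1 eil1-1 air replicate 1. No label says that replicates came from separate cultures, so differences between them may be technical.

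The comparison of EIN2C-EIN3DB in ein3-1 eil1-1 with Col gives the transcripts that differ from wild type in a line with the fusion and without intact EIN3 and EIL1. No untransformed ein3-1 eil1-1 RNA library is among the samples, so in all 3 lines the folds over Col cannot separate the transgene or its substitution from the double mutation. Col RNA libraries are not among the samples either. The treatment of Col, air or ethylene, is not given in the sources used here. Treatment, growth, library preparation or alignment that differed from Col therefore cannot be told apart from the genotype, also for the ethylene-induced genes below. The receptor genes ETR2, ERS2 and ERS1 and 16 of 28 known EIN3 targets were lower than in Col, and LHB1B1 and KIN1 were among the 10 largest increases. In the authors' deposited table the receptor gene ETR2 (AT3G23150) stood at log2 -5.57, the receptor gene ERS2 at -3.92 and EBF2, which encodes an F-box protein that removes EIN3, at -3.30. The light-harvesting gene LHB1B1 (AT2G34430) was higher by log2 9.59 and the cold-regulated gene KIN1 (AT5G15960) by 6.49 in the authors' deposited table. The engineered and mutated genes themselves were lower than in Col. In the authors' deposited table EIN2 (AT5G03280, chromosome 5, 787428 to 793356, TAIR10) had 43.6 FPKM and log2 -1.44, EIN3 (AT3G20770) had 38.2 FPKM and log2 -2.06, and EIL1 (AT2G27050) had 10.7 FPKM and log2 -2.86. A gene-level value of EIN2 or EIN3 cannot separate the resident gene from the fusion.

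Of 16 ethylene perception and signalling genes, 9 were lower in EIN2C-EIN3DB and 0 were higher in the authors' deposited table. This split differed from that of the other listed genes (two-sided Fisher's exact test, adjusted p = 0.0423). Besides the genes above, the authors' deposited table lists the receptor gene ERS1 at log2 -2.15, EBF1 at -1.34 and CTR1, a kinase gene that acts against the ethylene response, at -1.26. Of 28 EIN3 targets and ethylene-induced genes, 16 were lower and 1 was higher (adjusted p = 0.00748, two-sided Fisher's exact test), a list that shares ETR2, ERS2, EBF2, ERS1 and CTR1 with the signalling list. In the authors' deposited table ARL and ARGOS, both organ growth genes, stood at log2 -4.64 and -3.56, the flagellin receptor gene FLS2 at -4.55, and the transcription factor gene EDF3 at -2.99. The apical hook gene HLS1 stood at log2 -2.88 and PIF3, a light signalling gene, at -2.22 in the authors' deposited table. The exception was the tryptophan synthesis gene ASB1, higher by log2 1.16 in the authors' deposited table.

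No other list passed the adjusted test of higher against lower in this line. Auxin response and transport genes were 7 lower and 1 higher (adjusted p = 0.317), and their members were listed more often than other protein-coding genes (adjusted p = 0.0404 on membership, both two-sided Fisher's exact tests). Membership tests in each line were set against all protein-coding nuclear genes, unexpressed ones included. A list of expressed genes can therefore pass on membership more easily, and no match for expression was made. IAA19, in the authors' deposited table, stood at log2 -1.76, GH3.5 at -1.74 and IAA5 at 2.62. All 5 listed heat shock genes were lower, among them HSP22.0 at log2 -2.62 and HSP101 at -1.41 in the authors' deposited table. All 5 listed root hair genes were higher, among them the expansin gene EXPA7 at log2 3.62 and RHD6, a root hair regulator, at 3.10 in the authors' deposited table. Root hair genes passed on membership (adjusted p = 0.0210, two-sided Fisher's exact test) but not with a minimum level of 5, which left 2 of them. The photosynthesis list was 11 higher and 9 lower. Its 20 listed members of 27 were more than other protein-coding genes gave (adjusted p = 3.96e-08, two-sided Fisher's exact test on membership). LHCB1.1, LHCB1.2 and LHCB2.2, which encode light-harvesting proteins, stood at log2 5.66, 4.75 and 3.65 in the authors' deposited table. PORA, a protochlorophyllide reductase gene of dark-grown seedlings, stood at log2 -4.11 in the authors' deposited table. Near-identical LHCB1 copies can share reads, so their single values are uncertain.

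Smaller lists in EIN2C-EIN3DB passed neither test over all listed genes. On membership, ethylene biosynthesis and heat shock genes passed at a fold of at least 4, and cell wall and heat shock genes with a minimum level of 5. EIN3-repressed genes were 2 higher and 0 lower, with the cold regulators CBF1 and CBF2 at log2 3.41 and 1.71 in the authors' deposited table. Ethylene biosynthesis genes were 1 higher and 4 lower, with ACS5 at log2 -3.24 and ACO5 at -2.47 in the authors' deposited table. Cell wall loosening genes were 3 higher and 2 lower, with EXPA2 at log2 4.69 and XTH19 at -1.91 in the authors' deposited table. Jasmonate and ERF defence genes were 2 higher and 0 lower, both vegetative storage protein genes, VSP2 at log2 2.97 and VSP1 at 1.44 in the authors' deposited table. Seed storage genes were 4 higher and 1 lower, hypoxia genes 3 and 1, cell division genes 2 and 0, cytokinin genes 1 and 0, gibberellin genes 1 and 2, and histone acetylation genes 0 and 1. No salicylate defence or reference gene was listed.

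By size, the remaining leading increases in EIN2C-EIN3DB were BGLU18, a beta-glucosidase gene, at log2 6.44 and AT1G68250 at 6.48 in the authors' deposited table. Another 6 of the 10 largest increases, led by AT2G07698 at log2 8.97 in the authors' deposited table, lay in the stretch of mitochondrial sequence inserted in chromosome 2. All 90 plastid and mitochondrial genes in this table were lower and listed at 0 in the line. The 10 largest decreases held ETR2, ARL, AT5G19250 at log2 -6.12, AT3G51410 at -5.56, AT2G14060 at -5.38, AT1G20790 at -5.37 and the cellulase gene CEL2 at -4.72 in the authors' deposited table. In all, the authors' deposited table lists 5686 genes, 2797 higher and 2889 lower. At a fold of at least 4, 1444 genes were left, 851 higher and 593 lower, which raised the share of higher genes from 49.2% to 58.9%. At that fold the ethylene signalling list had 6 lower and 0 higher members in EIN2C-EIN3DB and in EIN2-S645A, and its split no longer passed. Its membership still passed in both lines, and its median log2 fold was -3.08 and -3.11 in the authors' deposited tables, against -2.15 and -2.16 over all its listed members.

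**Figure D1:**
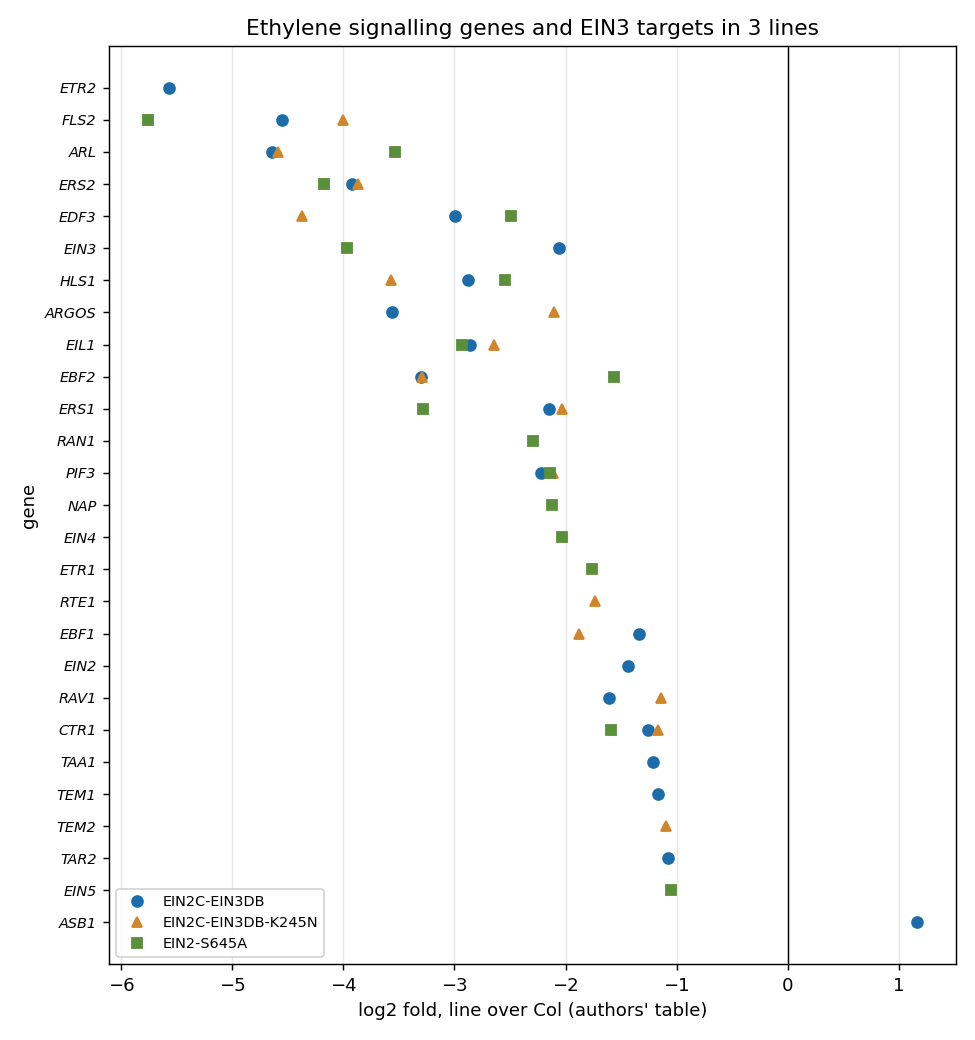
Log2 fold of each line over Col (horizontal axis, authors' deposited tables) for ethylene signalling genes and EIN3 targets (a selection of those listed in at least 1 line); 1 point per gene and line, with no replicate error. ETR2 lies at -5.57 and FLS2 at -5.76 at the left, and ASB1 at 1.16 is the only point above 0.

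The EIN2C-EIN3DB-K245N line asks the same with a substitution in the EIN3 part. The receptor genes ERS2 and ERS1 and 14 of 28 EIN3 targets were lower than in Col, the other receptor genes were not listed, and LHB1B1 had the largest increase by the rule for named genes. ERS2 stood at log2 -3.87, EBF2 at -3.30, ERS1 at -2.03 and EBF1 at -1.88 in the authors' deposited table. EIL1 stood at log2 -2.65 with 9.33 FPKM in the authors' deposited table, and EIN2 and EIN3 were not listed. EIN3 targets were 14 lower and 0 higher (adjusted p = 0.00694, two-sided Fisher's exact test). ARL, in the authors' deposited table, stood at log2 -4.59, EDF3 at -4.37, FLS2 at -4.00, HLS1 at -3.57 and ARGOS at -2.10. Ethylene signalling genes were 7 lower and 0 higher, which did not pass as a split (adjusted p = 0.142) but passed on membership (adjusted p = 0.0146, both two-sided Fisher's exact tests). RTE1, which encodes a partner of the receptor ETR1, was among them at log2 -1.74 in the authors' deposited table.

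LHB1B1 was higher by log2 10.57, LHCB1.1 by 7.82, LHB1B2 by 6.18 and LHCB1.2 by 5.53 in EIN2C-EIN3DB-K245N in the authors' deposited table. The photosynthesis list was 11 higher and 8 lower, and its members were listed more often than other genes (adjusted p = 4.12e-10, two-sided Fisher's exact test on membership). KIN1 and BGLU18 were higher by log2 6.24 and 6.44 in the authors' deposited table. Another 4 of the 10 largest increases lay in the chromosome 2 insertion, and all 81 listed organelle genes were at 0. Seed storage genes were 5 higher and 1 lower, with SESA3 at log2 5.14 and the cruciferin gene CRC at 3.14 in the authors' deposited table. CBF2 stood at log2 3.92, VSP2 at 3.81 and the ethylene synthesis gene ACS8 at 2.99 in the authors' deposited table. The auxin genes IAA29 and YUC8 stood at log2 2.13 and 1.47 in the authors' deposited table.

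The largest decreases in EIN2C-EIN3DB-K245N included AZI1, a defence priming gene, at log2 -5.92, CYP96A5 at -5.34, AT4G11610 at -4.99, HEC2, a bHLH transcription factor gene, at -4.96 and CEL2 at -4.29 in the authors' deposited table. No other list passed as a split. On membership, ethylene biosynthesis, cell wall and seed storage genes passed (adjusted p = 0.0177, 0.0162 and 0.0231, two-sided Fisher's exact tests). Ethylene biosynthesis genes were 2 higher and 4 lower, auxin genes 2 and 0, cell wall genes 3 and 2, EIN3-repressed genes 1 and 0, jasmonate genes 3 and 0, heat shock genes 0 and 3, hypoxia genes 2 and 0, root hair genes 2 and 0, cell division genes 1 and 0, histone acetylation genes 0 and 1, and gibberellin genes 0 and 1. Salicylate, cytokinin and reference genes were not listed. In all, 3721 genes were listed, 1806 higher and 1915 lower, and 934 at a fold of at least 4.

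The EIN2-S645A line, in the same double mutant, was compared with Col, and no unsubstituted EIN2 line is among the samples. LHB1B1 and LHCB1.1 had the largest increases among named genes, and EIN3, EIL1 and the receptor genes ERS2, ERS1, EIN4 and ETR1 were lower. In the authors' deposited table LHB1B1 was higher by log2 12.58, LHCB1.1 by 10.40, LHB1B2 by 7.48, LHCB1.2 by 7.40, LHCB2.2 by 6.85 and LHCB2.1 by 6.13. Near-identical LHCB1 copies can share reads here too. The photosynthesis list was drawn up as one of light exposure or greening, and neither was tested as a cause. EIN3 had 7.88 FPKM and log2 -3.97, EIL1 had 7.89 FPKM and log2 -2.93 in the authors' deposited table, and EIN2 was not listed. Ethylene signalling genes were 10 lower and 0 higher (adjusted p = 0.0357, two-sided Fisher's exact test). In the authors' deposited table ERS2 stood at log2 -4.17, ERS1 at -3.29, RAN1, a copper transporter gene of receptor assembly, at -2.30, EIN4 at -2.03 and ETR1 at -1.77. EIN3 targets were 11 lower and 0 higher (adjusted p = 0.0253) and did not pass on membership (adjusted p = 0.312, both two-sided Fisher's exact tests), though they did at a fold of at least 4. FLS2 stood at log2 -5.76, ARL at -3.53, HLS1 at -2.54, EDF3 at -2.49 and EBF2 at -1.57 in the authors' deposited table.

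The photosynthesis list in EIN2-S645A was 14 higher and 5 lower, which did not pass as a split (adjusted p = 0.147) but passed on membership (adjusted p = 2.3e-05, both two-sided Fisher's exact tests). KIN1 and its neighbour KIN2 were higher by log2 6.11 and 4.39 in the authors' deposited table. Another 5 of the 10 largest increases lay in the chromosome 2 insertion, and all 84 listed organelle genes were at 0. Large decreases included AT5G57760 at log2 -5.97, AZI1 at -5.42, AT2G35130 at -5.13, AT1G31920 at -4.88 and GRF7, a growth regulator gene, at -4.40 in the authors' deposited table. HAC1 and HAF1, which encode histone acetyltransferases, stood at log2 -2.12 and -1.996, and the glyoxylate cycle gene ICL at -2.73 in the authors' deposited table. The reference gene EF1A was higher by log2 1.21 in the authors' deposited table.

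The other lists in EIN2-S645A passed neither test over all listed genes, and seed storage genes passed on membership at a fold of at least 4. Ethylene biosynthesis genes were 1 higher and 4 lower, auxin genes 2 and 2, cell wall genes 2 and 2, EIN3-repressed genes 1 and 0, jasmonate genes 4 and 0, salicylate genes 0 and 1, seed storage genes 5 and 2, heat shock genes 0 and 5, hypoxia genes 1 and 1, root hair genes 2 and 0, cell division genes 1 and 0, histone acetylation genes 0 and 2, cytokinin genes 1 and 0, gibberellin genes 2 and 1, and reference genes 1 and 0. In all, 7357 genes were listed, 3354 higher and 4003 lower, and 2808 at a fold of at least 4. Higher genes had shorter loci than lower genes in this table, with medians of 1642.5 and 3158 bp, against 1953 and 2802 bp in EIN2C-EIN3DB and 2201 and 2323 bp in EIN2C-EIN3DB-K245N.

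**Figure D2:**
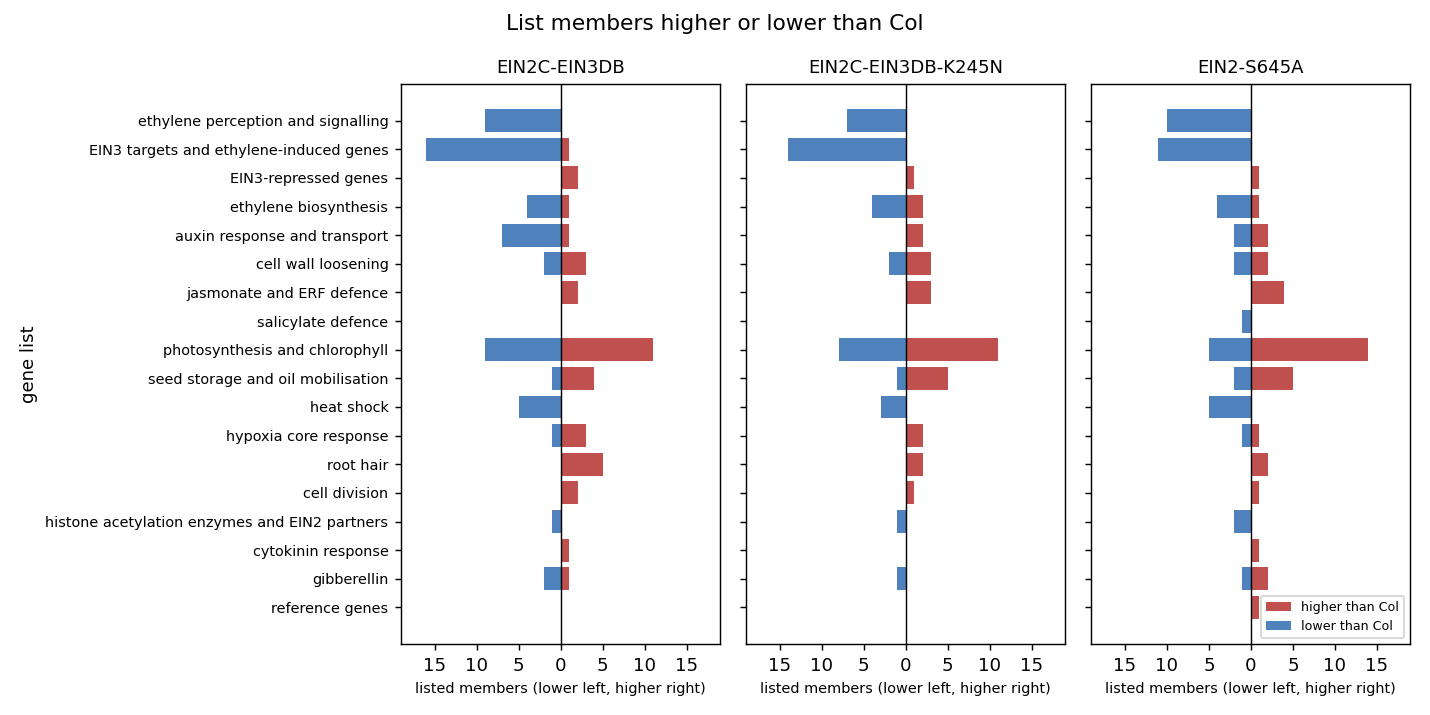
Members of each gene list that were lower (bars to the left) or higher (bars to the right) than Col in each line, as numbers of genes in the authors' deposited tables. EIN3 targets were 16, 14 and 11 lower against 1, 0 and 0 higher, and the photosynthesis list was 11, 11 and 14 higher.

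The lines were compared with each other through their calls against Col. The genes ERS2, ERS1, EBF2, CTR1, EIL1, ARL, FLS2, EDF3, HLS1 and PIF3 were lower in all 3 tables. LHB1B1, LHCB1.1, KIN1, BGLU18 and VSP2 were higher in all 3. Of 2559 genes listed in both fusion lines, 2556 (99.9%) had the same direction. EIN2C-EIN3DB and EIN2-S645A shared 3627 genes, 98.5% in the same direction, and EIN2C-EIN3DB-K245N and EIN2-S645A shared 2495, 98.9% in the same direction. Simulated lists of the same sizes, with no effect and 1 shared control, gave 98.63%, 97.13% and 98.07% for these pairs, so shares this high do not by themselves show a common effect. Simulated genes were called by list size alone, whereas the real lists passed the authors' q and fold limits. The simulation therefore cannot say what share of the real calls is error. The exact binomial intervals, 99.66 to 99.98, 98.03 to 98.86 and 98.38 to 99.25, lay above the simulated shares, but genes are not independent. At a fold of at least 4 the shares were 99.83%, 99.61% and 100%, against 99.93%, 99.78% and 99.85% simulated. There each interval held its simulated share.

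Among 27444 protein-coding nuclear genes, the fusion lines shared 1278 higher and 1094 lower genes, where independent lists would share 174.6 and 168.6. EIN2C-EIN3DB and EIN2-S645A shared 1601 higher and 1771 lower genes, against 322.5 and 369.7. EIN2C-EIN3DB-K245N and EIN2-S645A shared 1160 higher and 1127 lower genes, against 208.2 and 241.3. The ratios to independent lists ran from 4.67 to 7.32, and simulated lists of the same sizes with a shared control gave 2.97 to 3.74. At a fold of at least 4 the ratios were 10.2 to 27.4, against 5.66 to 9.90 simulated. With the listed genes of the 3 tables as background they were 1.64 to 2.57, against 1.64 to 2.03 simulated, and the lower genes of EIN2C-EIN3DB-K245N and EIN2-S645A fell below their simulated ratio of 1.76. Over all listed genes, against the 27444 genes, the odds ratios ran from 15.8 to 44.5. These all passed the two-sided Fisher's exact test at values below the smallest number that could be stored. The tables carry 1 set of Col values at different scales, so the control could not be split. The simulation assumes equal error in lines and control and was matched to list size after the data were seen, and the wide background holds unexpressed genes. It also treats every call as error, without the q and fold limits that the real lists passed. How much of the overlap comes from the shared Col values therefore stays open.

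The K245N substitution was set beside the unsubstituted fusion to ask what the substituted residue of the EIN3 part changes. DNA binding by the K245N fusion was not measured in these samples. ERS2, EBF2, ARL, EIL1 and PIF3 differed from Col by nearly the same amount in both: EBF2 stood at log2 -3.30 in each, and ERS2 at -3.92 and -3.87 in the authors' deposited tables. ARGOS stood at log2 -3.56 with the fusion and -2.10 with K245N in the authors' deposited tables. EDF3 went the other way, at log2 -2.99 and -4.37 in the authors' deposited tables. ETR2, EIN2 and EIN3 were listed for the unsubstituted fusion and not for K245N, which does not show that they differ between the lines. Of 2388 genes with finite values and 1 direction in both tables, 57.3% had the larger change in EIN2C-EIN3DB (exact binomial interval 55.3 to 59.3), with median absolute log2 folds of 1.65 and 1.56. Another 3127 genes were listed for EIN2C-EIN3DB alone and 1162 for EIN2C-EIN3DB-K245N alone. No test between the lines was possible without values per library, and the interval covers counting of genes, which are not independent.

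ChIP with the EIN2 antibody gives chromatin sites in lines that carry the fusion, in both backgrounds and treatments. Both backgrounds also hold the resident EIN2 gene and no library without the fusion is among the samples, so peaks cannot be assigned to the fusion. In Col-0 the strongest peaks by fold enrichment included those at CST, a kinase gene, BT2, a scaffold protein gene, and UBQ10 in the library titled air, and at EXO, a growth gene, SQD2, a sulfolipid gene, and AT5G25280 in ethylene. In ein3-1 eil1-1 the 10 strongest regions found in both replicates included UBQ10, ACT2, TIP2 and BT2 in air, and EBF2, PYK10, AT5G25280 and WRKY22 in ethylene. The strongest air region lay at no gene (chromosome 1, 14721995 to 14722122, mean 4.15-fold), and the ethylene region at 5580 to 5814 on chromosome 2 lay at the ribosomal RNA genes AT2G01010 and AT2G01020. The authors called 841 peaks in Col-0 air, 1510 in Col-0 ethylene, 252 and 255 in ein3-1 eil1-1 air, and 275 in ein3-1 eil1-1 ethylene replicate 2, with fewer in replicate 1. Fold enrichments and scores of peaks are the authors' own, depend on depth, and are compared only within a list, except that regions found in both replicates were ranked by the mean of their 2 folds. The numbers of peaks past a threshold are given per list and do not show a difference between libraries. At a fold enrichment of at least 5, 26 and 70 peaks were left in Col-0 and 0, 0, 1 and 0 in ein3-1 eil1-1. At a -log10 q of at least 5, 130 and 308 were left in Col-0, 32 and 34 in ein3-1 eil1-1 air, and 74 and 77 in ethylene. Backgrounds and depth cannot be separated, since Col-0 had 1 library per treatment and fewer tags after removal of duplicates.

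The leading Col-0 ethylene peak covered EXO (AT4G08950) on chromosome 4 from 5740032 to 5742099 (TAIR10), at a 13.6-fold enrichment. The AT5G25280 peak on chromosome 5, 8773850 to 8775381, had a 10.3-fold enrichment. In Col-0 air the leading peak lay at CST (AT4G35600) and AT4G35610 on chromosome 4, 16899424 to 16900190, at 9.36-fold. The peaks at BT2 and UBQ10 had 7.23-fold and 7.02-fold enrichment there. These Col-0 peaks were named after their values were seen.

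Between replicates of ein3-1 eil1-1, the peaks at EBF2, EIN2, EIN3 and UBQ10 recurred in both treatments. Some of these were weak: the EIN3 peak had a -log10 q of 0.16 in air replicate 2 and in ethylene replicate 1. In the 4 libraries the -log10 q ran from 0.05 to 3.64 for EIN2 peaks and from 4.03 to 7.39 for EBF2 peaks. In air 107 of 252 replicate 1 peaks overlapped a replicate 2 peak (42.5%, exact binomial interval 36.3 to 48.8). In ethylene 107 did as well (43.7%, interval 37.4 to 50.1). Random placement gave 0.0806% and 0.0592% (permutation p = 0.000999 in each, one-sided, the smallest that 1000 placements can give). Replicates of a treatment were called against 1 shared input, which random placement does not model, so their peaks are not independent. Without peaks whose implied input was at least 3 times the genome mean, a choice made after the data were seen, 30.7% were shared in air (59 of 192) and 11.03% in ethylene (15 of 136).

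Between air and ethylene, EBF2 and EBF1 carried Col-0 peaks in both. At EBF2 the library titled air had 3 peaks of 79 to 148 bp, and the ethylene library had 1 of 3096 bp (chromosome 5, 8793744 to 8796839) and 1 of 299 bp in the flank. At EBF1 the library titled air had 5 peaks of 79 to 187 bp, and the ethylene library had 1 of 3131 bp and 1 of 161 bp in the flank. With 1 Col-0 library per treatment, of different depth and with a conflicting label for air, these widths do not show an effect of ethylene. Of the Col-0 air peaks, 405 of 841 (48.2%) overlapped an ethylene peak, and 325 of 1510 ethylene peaks (21.5%) overlapped an air peak. In ein3-1 eil1-1, 49 of the 107 air regions found in both replicates (45.8%) overlapped an ethylene region, and single libraries gave 28.2 to 29.0%, against 42.5% and 43.7% between replicates of a treatment. These shares carry no test of the treatment. They moved with the overlap rule: under a reciprocal overlap of at least 50 percent Col-0 gave 21.9% and ein3-1 eil1-1 27.1%.

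Between backgrounds, the genes EBF2, EIN2, EIN3 and UBQ10 carried peaks in ein3-1 eil1-1 and in Col-0, although the air peaks at EBF2 lay at different places in the gene. In air 82 of 107 ein3-1 eil1-1 regions (76.6%, exact binomial interval 67.5 to 84.3) overlapped a Col-0 peak, where random placement gave 0.388%. In ethylene 80 of 107 did (74.8%, interval 65.4 to 82.7), where random placement gave 0.572%. Both had a permutation p of 0.000999, one-sided, the smallest possible. Of these regions, 43.9% in air and 85.0% in ethylene had high implied input, which random placement does not model. Without high-input peaks, a choice made after the data were seen, 38 of 59 regions (64.4%) overlapped in air and 12 of 15 (80.0%, interval 51.9 to 95.7) in ethylene. Single replicates gave 43.9 to 46.4% in air and 40.8 to 43.6% in ethylene. The EBF2 site of ein3-1 eil1-1 was narrow, 76 to 125 bp in the 4 libraries, and lay near 8796173 on chromosome 5 inside the broad Col-0 ethylene peak. At ACT2, an actin gene used as a reference, ein3-1 eil1-1 air had a region on chromosome 3 from 6476074 to 6476155, with no Col-0 peak there.

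**Figure D3:**
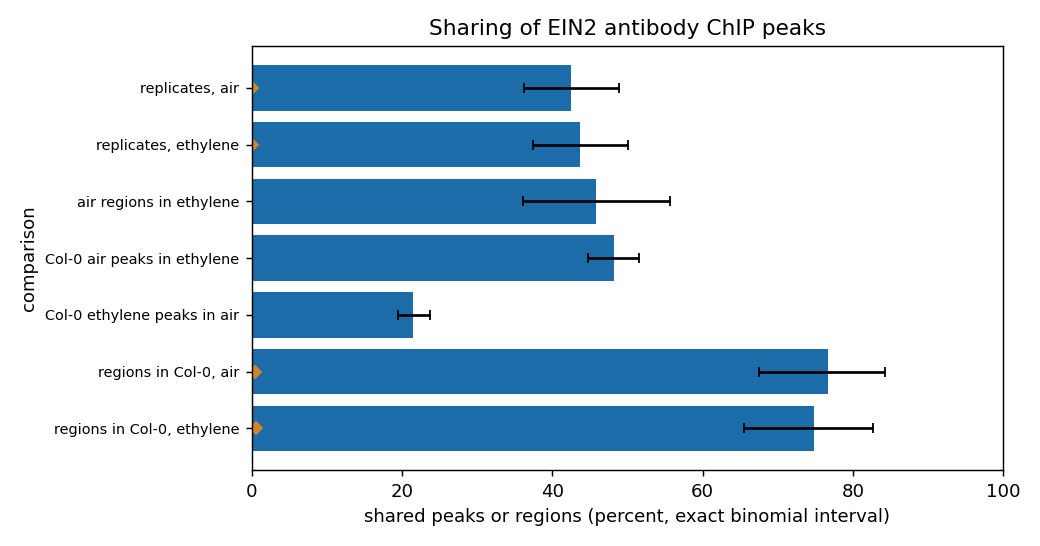
Percent of peaks or regions shared in each comparison (bars, with exact binomial intervals as whiskers), with the percent from random placement as diamonds where it was run. Replicates shared 42.5% and 43.7%, and 76.6% and 74.8% of ein3-1 eil1-1 regions overlapped Col-0 peaks.

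**Figure D4:**
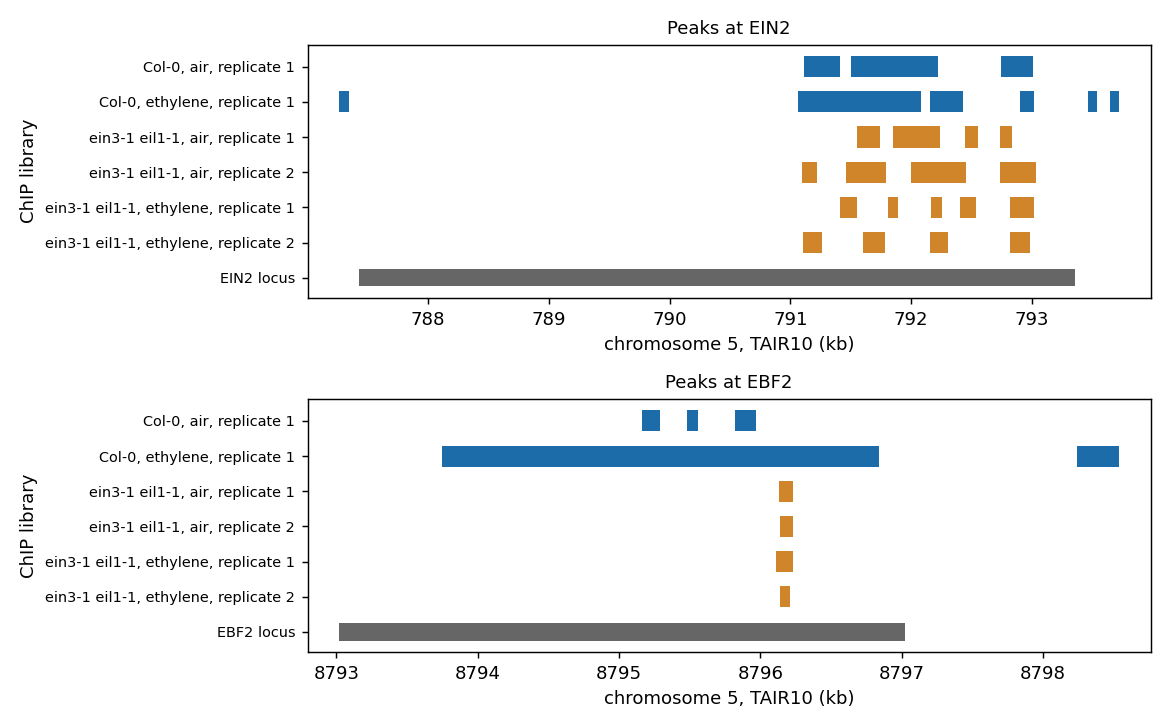
Position along chromosome 5 (kb, TAIR10) of the peaks within 1000 bp of EIN2 and EBF2 in the 6 ChIP libraries, in blue for Col-0 and orange for ein3-1 eil1-1, with the locus of the authors' deposited table in grey. Peaks over EIN2 itself lie from 791067 onward, and the Col-0 ethylene peak at EBF2 spans 3096 bp.

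Peaks were then placed at genes, within 1000 bp of either end. The ethylene signalling list passed the test in all 4 sets of peaks, EIN3 targets passed in Col-0 only, and ethylene biosynthesis genes passed in none. The signalling list holds EIN2 and EIN3, parts of which the fusion carries by its name, and no test was run without them. In ein3-1 eil1-1 the only other signalling gene with a region was EBF2. The passes there therefore do not show peaks at ethylene signalling genes beyond EBF2. In Col-0 ethylene, 12 of 28 EIN3 targets had a peak (1.35 expected from all protein-coding nuclear genes, adjusted p = 8.0e-08, two-sided Fisher's exact test). Among them were ARGOS, ARL, CTR1, EBF2, EDF3, HLS1, RAV1, TEM1 and TEM2. TEM1, a flowering repressor gene, had 7.28-fold, ARGOS 4.77-fold and ARL 4.64-fold enrichment. In Col-0 air 8 did (adjusted p = 2.67e-05, two-sided Fisher's exact test), among them CTR1, EBF2, HLS1, RAV1, TEM1 and TEM2. The signalling list had 6 genes with peaks in each Col-0 library (adjusted p = 6.88e-05 in air and 0.000589 in ethylene, two-sided Fisher's exact tests), CTR1, EBF1, EBF2, EIN2 and EIN3 in both, with ETR1 in air and EIL1 in ethylene. At a -log10 q of at least 5, 1 EIN3 target was left in Col-0 air and the list no longer passed. Lists were set against all protein-coding nuclear genes, unexpressed ones included, without a match for expression or locus length. Photosynthesis and reference genes also passed in some sets, as given below, so a pass is not particular to ethylene genes.

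In ein3-1 eil1-1, EBF2, EIN2 and EIN3 were the 3 signalling genes with a region found in both replicates in air (adjusted p = 6.88e-05) and again in ethylene (adjusted p = 7.84e-06, two-sided Fisher's exact tests). EBF2 was the only EIN3 target with such a region (adjusted p = 0.242 in air and 0.109 in ethylene, two-sided Fisher's exact tests). In ethylene replicate 2 alone, the signalling gene EIN5 and the EIN3 target ERF5 also had a peak, at 3.61-fold and 2.46-fold. Their -log10 q was 2.59 and 0.27. The peaks at EIN2 and EIN3 stood on raised input, with a median implied input of 4.48 times the genome mean over 21 peaks in ein3-1 eil1-1. Of the reference genes, ACT2 and UBQ10 had a region in air (adjusted p = 0.000498) and UBQ10 in ethylene (adjusted p = 0.0262, two-sided Fisher's exact tests). The ethylene calls of both lists rested on 3 genes and 1 gene, and none was left at a -log10 q of at least 5.

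Light, auxin and growth genes also carried Col-0 peaks. In air 13 of 27 photosynthesis genes did (adjusted p = 2.16e-11, two-sided Fisher's exact test), among them LHCA1, LHCB1.1, LHCB3 and RBCS1A. In ethylene 7 did (adjusted p = 0.00148, two-sided Fisher's exact test), among them PORB and RBCS1A. Auxin genes had 5 in air (adjusted p = 0.000925) and 6 in ethylene (adjusted p = 0.000776, two-sided Fisher's exact tests), with GH3.3, IAA2 and the auxin carrier genes PIN3 and PIN7 in both. XTH19, XTH22 and XTH24, wall enzyme genes, had peaks in ethylene (adjusted p = 0.0388), and CBF1 and CBF3 in air (adjusted p = 0.0306, two-sided Fisher's exact tests). Auxin genes in air, CBF genes in air and wall genes in ethylene had 0 members left at a -log10 q of at least 5.

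Genes with Col-0 peaks were among those lower in EIN2C-EIN3DB more often than other genes. The peaks came from plants with the fusion in Col-0. The calls came from the fusion in ein3-1 eil1-1, in air, against Col. Background therefore differed, and treatment too for the ethylene peaks, so these shares do not show binding at genes that the fusion lowers. EBF2, ARL, ARGOS and HLS1 had a Col-0 ethylene peak and were lower in the line. In all, 260 of 1323 genes at Col-0 ethylene peaks were lower (19.7%, against 9.70% of all protein-coding nuclear genes; odds ratio 2.42, adjusted p = 1.51e-28, two-sided Fisher's exact test). At Col-0 air peaks 149 of 851 were lower (17.5%, odds ratio 2.03, adjusted p = 3.53e-12, two-sided Fisher's exact test). Genes higher in the line did not pass at either set (odds ratios 1.202 and 0.910, adjusted p = 0.183 and 0.509, two-sided Fisher's exact tests). With the listed genes of the 3 tables as background, higher genes passed as fewer at Col-0 ethylene peaks (odds ratio 0.534), the Col-0 air ratio for them was 0.776 without passing, and lower genes still passed at 1.71 and 1.47 in ethylene and air. Among the 61 genes at ein3-1 eil1-1 air regions 8 were lower and 5 higher, and among the 24 at ethylene regions 3 were lower and 6 higher, none past the test (adjusted p from 0.0712 to 0.831, two-sided Fisher's exact tests). For the higher genes at ethylene regions the odds ratio was 3.03, and 1.07 to 1.67 with either replicate left out. The background holds unexpressed genes, because the set of genes tested by the authors is not used here. Lower genes in this line also had longer loci than higher genes, with medians of 2802 and 1953 bp. Longer loci can hold more peaks, and no length-matched test was run, so length cannot be separated from these ratios.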

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

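The tests of organelle genes, of RNA quality, of EIN3 target genes at recurring peaks and of the fusion's own sequence were chosen only after the result was seen. The 2 tests of locus length and the test of repeated sequence were written before their results, but reading air and ethylene separately in the last was decided after the values were seen.

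Genes listed in opposite directions in 2 lines were picked out because their calls against Col went apart, on pooled values and without a test of the difference. The fusion lines had 3 such genes: CRC, a seed storage gene, at log2 -2.17 in EIN2C-EIN3DB and 3.14 in EIN2C-EIN3DB-K245N in the authors' deposited tables, AT4G34881 at 1.19 and -1.13, and XIG, a myosin gene, at -1.18 and 1.055. EIN2C-EIN3DB and EIN2-S645A had 55 such genes, and EIN2C-EIN3DB-K245N and EIN2-S645A had 28. The last 2 of the genes named were chosen after their values were seen.

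Every listed plastid and mitochondrial gene, 90, 81 and 84 in the 3 tables, was listed at 0 in the line. A partial fall of organelle transcripts is argued against, since 100% of the listed organelle genes were at exactly 0 in each table. In contrast, every listed gene of the mitochondrial insertion on chromosome 2 was higher, 52 of 52, 42 of 42 and 40 of 40, so 100% in each table. A candidate explanation is that organelle reads were left out of the line libraries' alignment, or placed at nuclear copies, while Col was handled otherwise. The alignment itself is not given in the sources used here, and no biological explanation other than a partial fall was tested.

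Genes higher in EIN2-S645A and EIN2C-EIN3DB had shorter loci than lower genes, with ratios of median spans, lower over higher, of 1.92 and 1.43, and 1.06 in EIN2C-EIN3DB-K245N (bootstrap interval 0.998 to 1.102). Without 138 ribosomal protein, photosynthesis and organelle genes the ratio was 1.94 in EIN2-S645A (interval 1.89 to 2.001). So few of its 7357 listed genes could hardly move a ratio of medians, so this test says little about these groups. Length did not account for the lower EIN3 targets: draws of length-matched listed genes gave a one-sided permutation p of at most 0.000400 over the 3 lines. RNA quality or library preparation that differed from Col cannot be told apart from the lines, because 0 Col RNA libraries are among the samples. A difference between the lines themselves stays open and untested.

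Peaks in ein3-1 eil1-1 were few, and many recurred between libraries. Members of the signalling and EIN3 target lists held at most 5.61% of the regions found in both replicates (exact interval 2.09 to 11.8). Lists of 16 and 28 genes could hardly hold most of 107 regions, so this does not decide on EIN3 targets outside the lists. High implied input, which could come from repeated sequence piled up at single sites, was found in 85.0% of ethylene regions (interval 76.9 to 91.2), and 43.9% of air regions (interval 34.3 to 53.9) leave this open for air. At EIN2 and EIN3, extra copies of the fusion's own sequence may add input: the 21 peaks there had a median implied input of 4.48 times the genome mean (3.28 to 5.73), and the peaks inside EIN2 all lay beyond its midpoint. In Col-0 the medians in air and ethylene were lower, 2.55 and 2.22 at EIN2 and 1.53 and 1.23 at EIN3. Input was thus raised less there, but the values do not exclude raised input at the Col-0 peaks. Binding at these genes was not separated from input in ein3-1 eil1-1.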

How the results depend on the processing

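The alternatives with peaks moved by 10 to 100 kb, without organelle or insertion genes, without high-input peaks, with the gene body only, with the listed genes as background of the overlap, and those of the membership test were chosen after seeing the data. Of the values under alternatives, 178 for main results and 119 for others stayed the same. They kept direction and side of the threshold, stayed within error or, for counts, stayed within a fixed ratio of the main count. Among main results 29 moved, 14 reversed, 10 were weaker and 5 stronger, and among others 3 moved, 3 reversed and 9 were stronger. The sharing of peaks between replicates and between backgrounds, and the higher-against-lower calls of EIN3 targets in all 3 lines kept their direction and side of the threshold under every alternative run. So did the overlap of lines against independent lists. Against the simulated shared control, lower genes of EIN2C-EIN3DB-K245N and EIN2-S645A turned with the listed genes as background, at a ratio of 1.64 against 1.76. No paired analysis was possible because replicates 1 and 2 of the groups have no RNA values per library, and peak overlaps are values without a fit. Not run were the 4 motif alternatives, the upstream-only placement for both peak and gene results, and a replicate block.

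At a fold of at least 4, listed genes fell to 1444, 934 and 2808, genes in both fusion lines to 589, and list calls to 3; signalling genes kept 6 lower members in EIN2C-EIN3DB and 6 in EIN2-S645A without passing as a split, by construction on fewer genes. On membership, auxin genes in EIN2C-EIN3DB (odds ratio 1.31) and wall and ethylene biosynthesis genes in EIN2C-EIN3DB-K245N (9.75 and 6.20) no longer passed at that fold, and root hair genes in EIN2C-EIN3DB (1.88) no longer passed with a minimum level of 5. Gained on membership at a fold of at least 4 were ethylene biosynthesis (9.35) and heat shock genes (10.5) in EIN2C-EIN3DB, and EIN3 targets (3.86) and seed storage genes (7.24) in EIN2-S645A. With a minimum level of 5, heat shock and wall genes in EIN2C-EIN3DB (5.87 each) were gained. Without passing, the split of auxin genes in EIN2C-EIN3DB turned to 1 higher and 0 lower at a fold of at least 4, and that of photosynthesis genes, 6 higher and 5 lower, turned against the other genes. The same-direction share was then 99.83% for the fusion lines and 99.61% for EIN2C-EIN3DB with EIN2-S645A, below the simulated 99.93% and 99.78%. It was 100% for EIN2C-EIN3DB-K245N with EIN2-S645A, against 99.85% simulated. With log2(value + 1), 60.6% of genes had the larger change in EIN2C-EIN3DB. Peaks at a fold enrichment of at least 5 were 26 and 70 in Col-0 and 0, 0, 1 and 0 in ein3-1 eil1-1. At a -log10 q of at least 5 they were 130, 308, 32, 34, 74 and 77, by construction.

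The air peaks shared with ethylene in Col-0 were 80.8% at a -log10 q of at least 5, 21.9% under a reciprocal overlap of at least 50 percent and 26.4% for summits within 100 bp. In ein3-1 eil1-1 they were 58.8%, 27.1% and 35.5%, and from 28.2% to 29.0% with either replicate left out. For genes at peaks among genes called in EIN2C-EIN3DB, the Col-0 air odds ratio for higher genes passed at 1.97 with a -log10 q of at least 5 and at 1.44 with the gene body only. The ein3-1 eil1-1 ethylene odds ratio for higher genes passed at 6.06 with a -log10 q of at least 5, on 10 genes, and was 1.07 to 1.67 with either replicate left out, without passing. With the genes of the tables as background, the Col-0 ethylene odds ratio for higher genes passed as a depletion at 0.534, and without passing the Col-0 air ratio for higher genes turned to 0.776 and the ein3-1 eil1-1 ethylene ratio for lower genes to 0.875. Also without passing, the ein3-1 eil1-1 air ratio for higher genes turned to 1.01 and the ethylene ratio for lower genes to 0 at a -log10 q of at least 5. With either replicate left out these ran from 1.11 to 1.21 and from 0.585 to 0.997. The ein3-1 eil1-1 air odds ratio for lower genes ran from 1.08 to 1.79 with either replicate left out and passed without replicate 2. The cause was not tested.

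List calls at peaks fell to 9 at a -log10 q of at least 5. There, EIN3 targets in Col-0 air had 1 gene, and EIN3-repressed genes and auxin genes in Col-0 air, wall genes in Col-0 ethylene, jasmonate genes in Col-0 ethylene, and signalling and reference genes in ein3-1 eil1-1 ethylene had 0. EIN3-repressed genes in Col-0 air also had 0 with the gene body only. Wall genes in Col-0 ethylene had 3 within 2000 bp and did not pass, while jasmonate and ethylene biosynthesis genes there had 4 each and passed. Ethylene biosynthesis genes in Col-0 ethylene also passed, with 3, at a -log10 q of at least 5. Reference genes in ein3-1 eil1-1 ethylene had 1 with either replicate left out and did not pass. The cause was not tested. An effect of depth on the peak lists was not tested either: the Col-0 libraries kept the fewest tags, 3743192 and 4713282, and had the most peaks, 841 and 1510.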

Other observations

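The groups in this part were chosen after the data were seen, partly from genes that they hold, such as KIN1, so their counts are given without a test. Cold-regulated genes, which include dehydrins and other protective proteins, were 6 higher and 0 lower in EIN2C-EIN3DB, 6 and 0 in EIN2C-EIN3DB-K245N, and 5 and 0 in EIN2-S645A. COR15A was higher by log2 6.10 in EIN2C-EIN3DB in the authors' deposited table. COR413IM1 stood at log2 3.81, 4.15 and 4.31, and LTI65 at 1.54, 2.12 and 1.89 in the 3 lines in the authors' deposited tables. Genes of the ER body, a defence compartment of seedlings, were 2 higher and 0 lower in both fusion lines, with BGLU18 at log2 6.44 in each and TSA1 at 2.27 and 2.62 in the authors' deposited tables. In EIN2-S645A the list was 1 and 1, with BGLU18 at log2 2.88 and PYK10 at -1.26 in the authors' deposited table.

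Ribosomal protein genes were 32 higher and 2 lower in EIN2C-EIN3DB and 33 and 2 in EIN2-S645A. In EIN2C-EIN3DB-K245N they were 6 higher and 9 lower, and the difference between lines was not tested. The 67 genes were picked by the words ribosomal protein in their symbols or synonyms, so genes named otherwise were left out. The list mixes plastid with other ribosomal protein genes, which were not counted apart. RPS13A was higher by log2 2.69 with the fusion and by 1.79 with K245N in the authors' deposited tables. RPS15A and RPS28 were higher by log2 3.64 and 3.46 in EIN2-S645A in the authors' deposited table. The plastid ribosomal protein genes PSRP3/1 and PRPL28 stood at log2 -1.92 and -1.56 with K245N in the authors' deposited table. The lines with 32 and 33 of them higher are those with the larger ratios of median spans given above, 1.43 and 1.92.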
